A study of Rattus norvegicus with 6 samples.

How the data were processed

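Small RNA libraries were sequenced from wild-type, untreated fibroblasts of rat sciatic nerve. Of the 6 samples, 3 were made from the extracellular vesicles (EV, called exosomal in the labels) of the fibroblasts and 3 from RNA inside the cells (Intracellular), the controls of the design. The labels put all samples in 1 batch. They do not say whether the replicates were separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

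Per the labels' protocols, RNA was isolated with a miRNA kit, adapters were ligated to the 3' and then the 5' end, and the cDNA was amplified by PCR and cut from a gel. Adapter ligation and PCR favour some sequences over others, and no molecular identifiers are named, so floors cover counting error only. Per the submitters' processing notes, cutadapt was used and the genome build was Rnor_6.0. The aligner, the miRNA database and the counting program are not given in the sources used here. Coordinates are not given, since the gene table at hand is of another build.

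The deposited count table holds whole-number counts per mature miRNA, made by the authors from their reads. It has 1071 rows, of which 552 are known rat miRNAs and 519 are miRNAs predicted by the authors. Of all rows, 39 join several miRNA names. How reads shared between near-identical family members (let-7, miR-30, miR-29) were divided is not stated, so single members of such families are uncertain. The deposited TPM table, also made by the authors, equals the counts scaled to 1000000 per library with no length term, with a largest difference of 4.8e-05. Columns were matched to samples by group and replicate number in their names.

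Totals ranged from 81211 to 105578 counts in the EV libraries and from 1839047 to 8859302 in the Intracellular ones. The mean Intracellular total was 50.2 times the mean EV total, and 1 count stood for 9.47 to 12.3 CPM (counts scaled to 1000000 per library) in EV libraries. A level at 0 was bounded by the floor of 3 counts over the pooled Intracellular libraries, 0.214 CPM.

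Counts were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and robust dispersions, EV minus Intracellular, without a replicate block, 2-sided, at a Benjamini-Hochberg adjusted p under 0.05. A call is a miRNA past that threshold. The filter scales its minimum count to the median library size, so miRNAs could pass with fewer than 10 counts in every EV library. Some higher calls therefore rest on few EV counts in all, such as miR-138-5p (7) and miR-96-5p (8). Standard errors were taken from the F statistic. The procedure was also run on counts simulated at these library sizes, from pooled means and the fitted trend of dispersion. With 364 miRNAs in the step, the procedure recovered 26.2% of miRNAs changed 1.5-fold, 50.0% of those changed 2-fold and 88.9% of those changed 4-fold. It called 1.76% of unchanged ones. About as many miRNAs were raised as lowered, and single miRNAs did not vary around the trend. These rates may therefore not apply to the real data, where calls depended on the scaling.

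Before the data were examined, 21 lists of miRNAs were fixed: families (let-7, miR-29, miR-30, miR-15 and miR-16, miR-34, miR-181), genomic clusters, markers of cell types, EV-associated miRNAs from the literature and non-canonical miRNAs. Of these, 17 had the required 3 tested members and were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and fry as alternatives. Values per library were compared by 2-sided exact permutation tests, for which 3 against 3 samples give no p below 0.1. Arms of a precursor were compared as log2 of the minor over the major arm with a prior count of 1.

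Named miRNAs followed a rule fixed before the data were examined: the 10 largest changes in each direction among calls with at least 50 CPM in a group and no overlap of CPM, the 5 most abundant of each group, and up to 4 members of each list by mean CPM. The 10 known miRNAs with the largest rise under the same limits on CPM and overlap were added after the values were seen, since the rule gave predicted miRNAs alone for that direction. The miRNAs miR-152-3p, miR-214-3p, miR-138-5p, miR-667-3p and miR-92a-3p and the predicted novel540_mature were also chosen after their values were seen.

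Alternatives fixed before the data were examined were other scalings (RLE, total count, upper quartile, TMM without the 10 most abundant miRNAs), other filters, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), a fold threshold of 1.5, known miRNAs alone, a block for replicate number and each library left out, with the filter applied again to the libraries that stayed. Thinning of the Intracellular libraries to the median EV total of 92329 counts (20 draws) was added after the data were seen. Because the filter then tested fewer miRNAs, thinning and leaving out libraries were also run on the 328 rows tested at full depth. That second version was added after the results of the first were seen, and both are given.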

Results

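Small RNA was profiled in 3 EV samples and 3 Intracellular samples of fibroblasts from rat sciatic nerve, to compare the miRNAs in the vesicles with those in the cells. The EV libraries held 81211, 105578 and 92329 counts for replicates 1, 2 and 3. The Intracellular libraries held 1839047, 3313075 and 8859302. Pearson's r of log2 CPM across the tested miRNAs, which are not independent replicates, was 0.902 to 0.920 within EV, 0.985 to 0.996 within Intracellular and 0.778 to 0.857 between the groups. Intracellular replicate 1 stood apart in its TMM factor of 0.557, against 0.963 and 0.935 in the other Intracellular libraries. Every pair of libraries within a group differed by more than counting noise (chi-square per degree of freedom of 3.84 or more).

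The same miRNAs led both groups. miR-143-3p, a miRNA abundant in mesenchymal cells, took 197030 ± 12803 CPM in EV and 219151 ± 10544 CPM in Intracellular libraries (SD, n = 3). It was followed by miR-21-5p (129126 ± 5937 against 152971 ± 11468 CPM), let-7i-5p (74625 ± 5305 against 96243 ± 15410 CPM), miR-199a-3p (68490 ± 4040 against 72489 ± 2046 CPM) and let-7f-5p (49709 ± 2924 against 66083 ± 5894 CPM). The 10 most abundant miRNAs of each library took 66.0% ± 0.182 of counts in EV and 75.1% ± 4.33 in Intracellular libraries (SD, n = 3; exact permutation p = 0.1, the smallest the design allows).

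miR-122-5p, the dominant miRNA of liver cells, stood at 12119 ± 1398 CPM in EV and 194.7 ± 129.9 CPM in Intracellular libraries (SD, n = 3). This was a log2 fold change of 5.09 (SE 0.91, edgeR adjusted p = 0.0128), and of 6.33 (adjusted p = 1.67e-14) without Intracellular replicate 1, which held 344.7 CPM of it against 117.7 and 121.7 in replicates 2 and 3. miR-423-5p rose by 3.27 (SE 0.22, edgeR adjusted p = 6.38e-10), from 414.6 ± 35.5 to 6359 ± 505 CPM, and miR-378a-3p, encoded within Ppargc1b, rose by 2.65, from 408.8 ± 154 to 3873 ± 1289 CPM. miR-486, an erythroid miRNA, rose by 5.69 and the muscle miRNA miR-206-3p by 4.52, but these rest on 39 and 25 EV counts. Log2 rises of 5.29 for miR-3473, 3.98 for miR-345-5p, 3.73 for miR-760-3p, 3.31 for miR-3553 and 2.61 for miR-183-5p completed the 10 known miRNAs with the largest rise among calls with at least 50 CPM in a group and no overlap of CPM. In the same order these rest on 150, 20, 25, 19 and 58 EV counts.

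Among lower calls with at least 50 CPM in a group and no overlap of CPM, miR-127-3p of the imprinted Dlk1-Dio3 region fell by 1.67 (SE 0.29, edgeR adjusted p = 0.000159), from 20469 ± 2425 to 10753 ± 637 CPM. It was followed within that set by miR-30c-2-3p (-1.38), let-7e-5p (-1.21), let-7f-5p (-1.14), let-7i-5p (-1.12), miR-361-3p (-1.11), miR-98-5p (-1.04), miR-99a-5p (-0.99) and miR-21-5p (-0.97) on the log2 scale. Of these, miR-30c-2-3p rests on 13 EV counts and miR-361-3p on 41. With total-count scaling miR-127-3p (-0.92), let-7f-5p (-0.41) and let-7i-5p (-0.36) were the 3 miRNAs still called lower.

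Of 328 miRNAs tested, 84 were higher and 56 lower in EV with TMM scaling, and 107 higher and 3 lower with total-count scaling. The share of calls that were higher was 60.0% and 97.3%. The median log2 fold change of all tested miRNAs was -0.06 and 0.55, a shift of 0.61. All 84 higher calls were also called with total counts, while 9 of the 56 lower calls had a log2 fold change above 0 there, so that lower calls hold relative to the TMM reference. CPM, which carry no TMM scaling, did not overlap between the groups for 84 of the higher and 11 of the lower calls. The share without overlap was 45.4% of all tested miRNAs, against 10% by chance. These shares do not bear on the TMM calls, since the 2 scalings differ by the shift of 0.61. Some miRNAs also pass the filter only through their EV counts. Among the higher calls, 54 exceeded 4-fold, 32 of them known. Without Intracellular replicate 2 or 3, 50 were higher and 27 lower, as the scaled filter then left only 195 miRNAs to test. With the tested rows kept, 74 were higher and 43 lower without Intracellular replicate 2, and 78 and 36 without Intracellular replicate 3. Without EV replicate 1, 26 were lower with the filter applied again. With the filter applied again miR-122-5p lost its call without EV replicate 1 (log2 fold change 5.11, edgeR adjusted p = 0.0518) and without EV replicate 2 (5.11, adjusted p = 0.0693), but with the tested rows kept it held (adjusted p = 0.0468 and 0.0401), in an adjusted p range of 1.61e-26 to 0.0693 over its alternatives. Among the other named miRNAs, the higher calls of miR-29b-3p, miR-27a-3p, miR-34c-5p, miR-34a-5p and miR-96-5p were lost without at least 1 library. Of the 21 named lower calls, let-7f-5p, let-7i-5p, miR-21-5p, miR-99a-5p and miR-30c-2-3p were among 13 lost in this way with the filter applied again. Counting also the losses with the tested rows kept, 15 were lost.

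**Figure D1:**
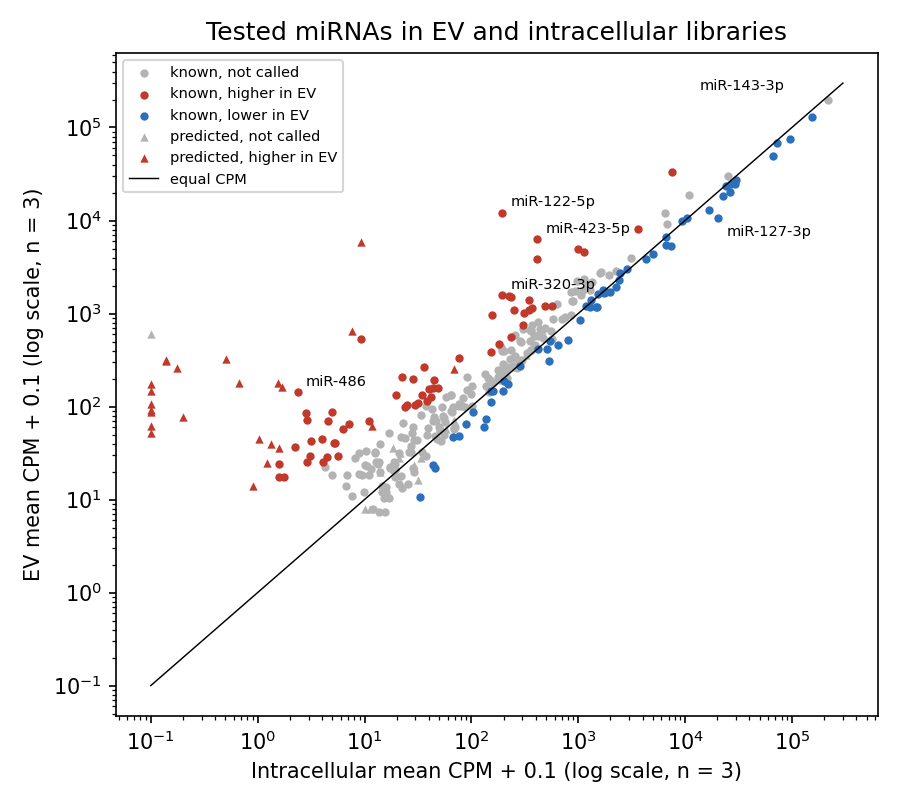
Mean CPM of each tested miRNA in the 3 EV libraries (vertical, log scale) against the 3 Intracellular libraries (horizontal, log scale), each with 0.1 added. Circles are known and triangles predicted miRNAs, red and blue mark the 84 higher and 56 lower calls with TMM scaling (107 and 3 with total counts), and the line marks equal CPM.

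**Figure D2:**
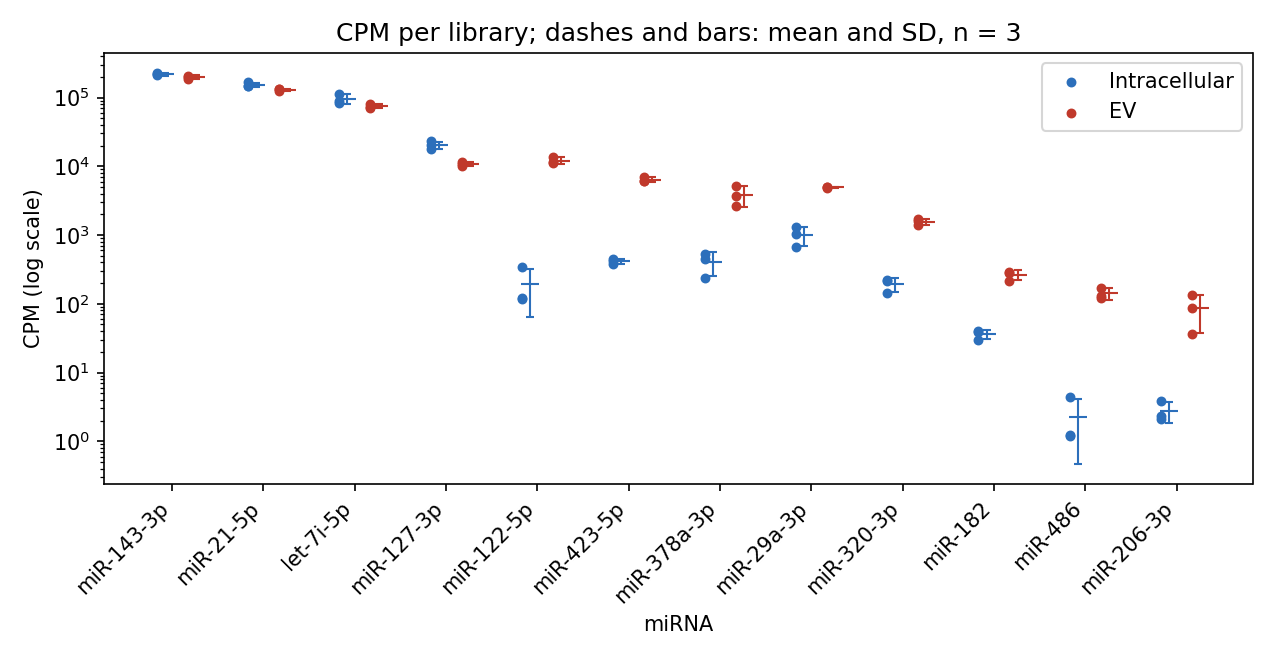
CPM (log scale) of 12 named miRNAs in each library, with points for the 3 libraries of a group and dashes and bars for their mean and SD. miR-122-5p stands at 12119 CPM in EV and 194.7 CPM in Intracellular libraries, while miR-143-3p is at 197030 and 219151 CPM.

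Predicted miRNAs took 1.36% ± 0.519 of EV counts and 0.142% ± 0.0382 of Intracellular counts (SD, n = 3; exact permutation p = 0.1). Of those tested, 24 of 38 were called higher, against 60 of 290 known ones. These shares are not compared by a test, since a miRNA with few Intracellular counts passes the filter only through its EV counts. The most abundant in EV, novel540_mature, was at 5830 ± 2286 CPM against 9.14 ± 5.09 CPM (log2 fold change 8.71, edgeR adjusted p = 4.21e-11). The 10 largest rises under the fixed rule were all of predicted miRNAs. Of these, novel236_mature, novel419_mature, novel109_mature, novel49_mature, novel305_mature, novel324_mature and novel399_mature had 0 Intracellular counts, against 50, 43, 31, 26, 26, 18 and 15 in EV. Their pooled EV levels were 837, 720, 519, 435, 435, 301 and 251 times the floor of 3 pooled Intracellular counts. These folds leave out the counting error of EV. Without EV replicate 2 they were 565, 431, 269, 350, 188, 161 and 161. The others, novel165_mature, novel341_mature and novel80_mature, had 1, 1 and 2 Intracellular counts against 93, 87 and 75 in EV. In EV replicates 1, 2 and 3, novel165_mature was at 160.1, 644.1 and 130 CPM. In the same order novel341_mature was at 394, 331.5 and 216.6 CPM and novel80_mature at 221.6, 445.2 and 108.3 CPM.

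Calls were also counted within the fixed lists. In the sensory cluster all 3 tested members rose, miR-183-5p by 2.61, miR-182 by 2.24 and miR-96-5p by 1.71, the last from 8 EV counts and lost without any 1 EV replicate (adjusted p 0.112, 0.0695 and 0.309 without replicates 1, 2 and 3). Of the non-canonical miRNAs, which bypass a step of the usual processing, 4 of 5 rose: miR-451-5p (3.71), miR-320-3p (2.39), miR-484 (1.48) and miR-1839-5p (1.43). Of the EV-associated miRNAs 3 of 4 rose: miR-486, miR-451-5p and miR-320-3p, from 39, 10 and 434 EV counts. miR-451-5p and miR-320-3p are in both of these lists, and miR-486 and miR-451-5p are also the tested erythroid miRNAs. Results of these lists are therefore not separate. In the let-7 family, 7 of 13 members fell and 0 rose with TMM scaling, but 2 fell and 1 rose with total counts.

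By camera, 0 of 17 lists passed an adjusted p of 0.05, with 4 at an unadjusted p under 0.05. These were the let-7 family (lower) and the sensory, EV-associated and non-canonical lists (higher), each with an adjusted p of 0.0625. With an estimated correlation their adjusted p was 0.724, 0.388, 0.388 and 0.388. Without EV replicate 2 the let-7, sensory and EV-associated lists each reached an adjusted p of 0.0369 with the filter applied again, but not with the tested rows kept (let-7 family 0.0877). The let-7 family reached 0.0109 and 0.0188 without Intracellular replicates 2 and 3, where Intracellular replicate 1 weighs more, and 0.190 without replicate 1. That library, which stood apart in its TMM factor, held 30.2% of its counts in this family, against 24.1% and 23.9% in Intracellular replicates 2 and 3. By fry, which does not compare a list with other miRNAs, 4 lists were higher and 1 was lower: sensory (adjusted p 9.89e-05), non-canonical (0.00104), EV-associated (0.00381), liver and serum (0.00918) and, lower, the miR-30 family (0.0245).

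The fibroblast and mesenchymal list took 51.9% ± 1.19 of EV counts and 54.8% ± 0.546 of Intracellular counts (SD, n = 3; exact permutation p = 0.1). Of its 23 tested members 6 were higher and 9 lower, or 8 and 0 with total counts. miR-152-3p rose from 7535 ± 1989 to 33332 ± 11552 CPM (log2 fold change 1.51) and miR-214-3p by 1.53. The miR-30 family had 0 higher and 4 lower of 10, or 1 and 0 with total counts. The Dlk1-Dio3 cluster had 9 higher and 8 lower of 58, or 15 and 1 with total counts. Among the higher was miR-667-3p (3.21, from 12 EV counts). The miR-17-92 and paralogous clusters had 3 higher and 1 lower of 11 (4 and 0 with total counts), with miR-92a-3p at 2.53, from 17 EV counts. Of the miR-29 family both tested members rose, miR-29a-3p by 1.70 and miR-29b-3p by 1.02. The miR-23, miR-24 and miR-27 clusters had 2 higher, with miR-23a-3p at 1.39, and 1 lower of 9 (3 and 0). The miR-34 family had 2 higher of 5 (3 with total counts), the miR-15 and miR-16 family 1 higher of 7, miR-503-5p at 1.52, and the miR-181 family 1 lower of 6 (0 with total counts).

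Among markers of other cell types, both tested erythroid miRNAs rose (miR-486 and miR-451-5p, 39 and 10 EV counts). In the liver and serum list 1 of 3 rose, miR-122-5p. By edgeR with TMM scaling, miR-192-5p and miR-194-5p had log2 fold changes of 0.15 (adjusted p 0.664) and 0.14 (adjusted p 0.723). With total counts these were 0.74 (adjusted p 0.188) and 0.72 (adjusted p 0.222). This list took 1.25% ± 0.136 of EV counts and 0.0430% ± 0.00410 of Intracellular counts (SD, n = 3). The muscle list had 1 higher (miR-206-3p) and 1 lower (miR-499-5p, -1.48) of 3, the latter not called with total counts. The neuronal list had 1 higher (miR-138-5p, 3.28, from 7 EV counts) and 2 lower (miR-9a-5p, -0.89, and miR-128-3p, -0.62) of 8, or 1 and 0 with total counts. None of the 3 myelinating glia, 3 leukocyte and 2 endothelial miRNAs tested was called with edgeR and TMM, and 1, the leukocyte miR-155-5p, had an unadjusted p under 0.05. It was called with total counts (log2 fold change 1.21, adjusted p 0.0256). No epithelial miRNA passed the filter.

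Adjusted over the list alone, the counts of higher and lower members were the same except for the fibroblast list (7 and 10), the miR-23, miR-24 and miR-27 clusters (1 and 0), the miR-30 family (0 and 6) and the Dlk1-Dio3 cluster (8 and 6).

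**Figure D3:**
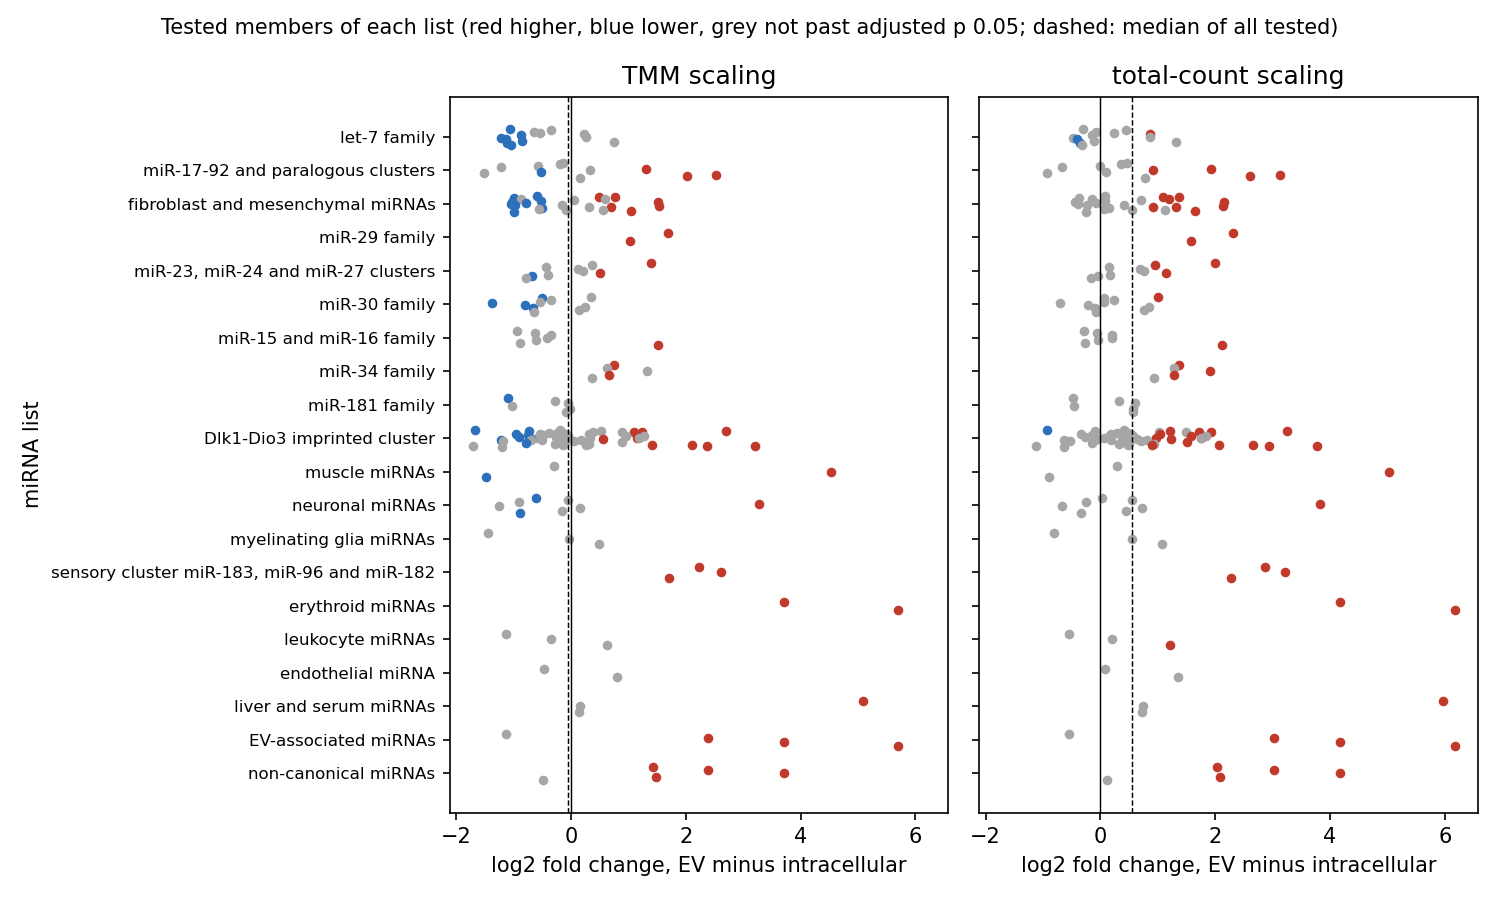
Log2 fold change (EV minus Intracellular) of each tested list member, with TMM scaling on the left and total-count scaling on the right; red and blue points passed adjusted p 0.05 as higher and lower. The dashed line marks the median of all tested miRNAs, -0.06 and 0.55, and the let-7 family has 7 lower members on the left and 2 on the right.

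The number of miRNAs with at least 1 count was 478.3 ± 27.4 in EV and 734.7 ± 147 in Intracellular libraries (SD, n = 3; exact permutation p = 0.1). With every library thinned to 81211 counts it was 462.7 ± 20.5 in EV and 315.7 ± 26.0 in Intracellular libraries, in the opposite order (exact permutation p = 0.1). Known miRNAs alone then numbered 320.3 ± 3.79 and 283.3 ± 16.2, and predicted ones 142.3 ± 17.0 and 32.3 ± 10.1. For 73 precursors with both arms tested, the median log2 ratio of minor to major arm was -2.72 ± 0.27 in EV and -2.74 ± 0.27 in Intracellular libraries (SD, n = 3; exact permutation p = 1). Its difference of 0.02 lay within the spread between replicates, and its sign turned with a prior count of 0.25 (-0.307).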

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

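The tests of blood, of liver or serum RNA and of depth for the predicted miRNAs were chosen after the result was seen. So were those of second arms among mature rows alone and of thinned fits with the tested rows kept. The same holds for depth for miR-122-5p and miR-486 alone and for miR-206-3p alone. Thinning of the Intracellular libraries was added after the data were seen. Thinning every library to the smallest was planned for the number of miRNAs detected.

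Below the filter, 23 miRNAs had counts in all 3 EV libraries and 0 in the 3 Intracellular libraries, although those are deeper, while 109 had counts in all 3 Intracellular libraries and 0 in EV, where at most 4.44 counts were expected. All of the 23 are predicted miRNAs, with 3 to 13 EV counts each. These 23 were singled out as a signal in data the comparisons do not use.

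The rise of miR-122-5p, miR-486, miR-451-5p and miR-206-3p was set against the low depth of the EV libraries. With the Intracellular libraries thinned and the filter applied again, miR-451-5p and miR-206-3p were not tested in any of the 20 draws. With the tested rows kept, the smallest median log2 fold change of the 4 was 2.58, for miR-451-5p, whose median adjusted p of 0.0784 (called in 9 of 20 draws) leaves a depth effect possible, although thinning also removes counts that a call needs. miR-122-5p and miR-486 were called in 20 of 20 draws either way, with medians of 5.39 or more (lowest draws 5.25 and 3.10). miR-206-3p was called in 20 of 20 with the tested rows kept, with a median of 3.81 (2.92 to 5.88 over the draws, 4.52 at full depth). For miR-122-5p this argues against depth as the whole cause. At 92329 counts 1 count is 10.8 CPM, above the Intracellular means of miR-486 (2.27 CPM) and miR-206-3p (2.76 CPM). Thinned libraries thus hold few or no counts of miR-486 and miR-206-3p. Their calls then rest on their 39 and 25 EV counts, so thinning cannot decide on depth for them. Blood would bring more miR-451-5p and miR-486 than miR-122-5p, but miR-122-5p was at least 51.8 times their sum in every EV library. That bears on miR-122-5p alone and leaves blood possible as a source of miR-486 and miR-451-5p. Liver or serum RNA, for instance from a culture medium, may still be the source of miR-122-5p. The larger log2 fold change of miR-192-5p and miR-194-5p was 0.15 with TMM scaling and 0.74 with total counts. The share of these miRNAs in such RNA is unknown. Vesicle sorting also stays open.

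The higher level of predicted miRNAs in EV was set against depth and against wrong predictions. With all libraries thinned to the smallest, at least 126 of all predicted miRNAs were detected in each EV library and at most 43 in each Intracellular one, a gap of 83, which argues against depth for the predicted miRNAs as a set but says nothing of single ones. A second arm with counts was found for 8.33% of the 24 called higher and for 5 of the 11 others, star rows left out (Fisher's exact p = 0.0207). Fragments of other RNAs, or RNA of another source, may therefore be among them, but the called ones also had fewer counts (median 46.5 against 504), which makes a second arm harder to see. No biological explanation was tested.

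Higher calls among known miRNAs were unevenly spread over GC content. Across 290 known miRNAs, which are not independent replicates, Spearman's rho of GC content with log2 fold change was 0.30 and Pearson's r was 0.32 (permutation p = 1e-05, the smallest they can give, and 3e-05 adjusted over 3 relations). The median was -0.30 for the 100 with at most 43.5% GC (12 called higher, 26 lower), -0.33 for the 99 with 44 to 50% (14 and 23) and 0.42 for the 91 with at least 52.2% (34 and 7, with 50 not called), so the difference lay in the last of these and was not a steady rise. Deviations of single libraries from their group mean followed GC content with a rho of at most 0.07 in size. For the Intracellular libraries (0.03, 0.05 and -0.05) this argues against a bias that varies from library to library. In the EV libraries (-0.04, 0.07 and -0.03) low counts would weaken any such relation, so such a bias stays possible there. A bias shared by all EV libraries may also remain and cannot be separated from the groups here. For the GGAG or CCCT motif the difference after removal of the GC trend was -0.07 (permutation p = 0.75, interval -0.48 to 0.34), which leaves it open: the limit set in advance was a p, and that does not exclude a small difference.

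The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 140 calls and the highest other 0, so the 1 split as large was the real one itself. Every other split mixes EV and Intracellular libraries in both groups, so a difference between them adds to the spread within groups. Few calls would then follow in any case, and 140 against 0 is no separate evidence. For the lists, the real split gave 0 calls and the highest other 2, with 10 splits as large. Any split is as large as 0, so this comparison tests nothing.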

How the results depend on the processing

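Thinning of the Intracellular libraries, the thinned number of known miRNAs and runs on the 328 rows tested at full depth were added after the data were seen. The last were added after the refiltered results. Thinning every library to the smallest for the number of miRNAs detected was planned. Without a named cause, the cause was not tested. Against 84 higher, 56 lower and 140 in all: no filter gave 197 higher and 268 in all, a mean of 10 CPM 155 and 225 (both test more rows) and DESeq2 153 higher. Lower were 3 with total count, 92 with upper quartile, 37 among known miRNAs, and 4, 2 and 2 with limma on log2(TPM + 1), log2(TPM + 0.1) and the unfiltered table. A fold threshold of 1.5 gave 8 lower and 72 in all. Leaving out 1 library gave 50 to 69 higher, 26 to 55 lower and 77 to 121 in all with the filter applied again (195 to 380 tested). With the tested rows kept it gave 62 to 91, 18 to 58 and 80 to 149: 18, 26 and 36 lower without EV replicates 1 and 2 and Intracellular replicate 3, and 80 and 91 in all without EV replicates 1 and 2. Thinning gave 44 higher, 20 lower and 63.5 in all (median 173.5 tested), or 63.5, 22 and 87 with the rows kept. Whether the replicate numbers pair the samples could not be told. Correlations of deviations were 0.035, 0.092 and -0.02 at the same number and -0.084 to 0.024 at different numbers. Low EV counts would weaken any such correlation. The replicate block gave 87 higher and 46 lower.

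Lists called were 0 higher and 0 lower by camera; fry gave 4 and 1, leaving out 1 library 0 to 2 and 0 to 1, thinning 1 and 1. With rows kept, 1 was lower without Intracellular replicate 2, without Intracellular replicate 3 and with thinning: the let-7 family each time.

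EV minus Intracellular detected miRNAs turned from -256.3 to 147 thinned and 37 for known miRNAs thinned, as depth differs. The 164.3 at 10 CPM is set by that threshold, since 1 count is 10.8 and 12.3 CPM in EV replicates 3 and 1. The arm difference turned to -0.307 with a prior count of 0.25 and ran from -0.114 to 0.169 with 1 library left out. Called lower with TMM, miR-25-3p reversed to 0.10 with total count and 0.13 in all 3 limma runs on TPM, miR-30a-5p to 0.07 and 0.15, 0.16 (log2(TPM + 0.1)) and 0.15, miR-128-3p to 0.027 and 0.04, and miR-30d-5p to 0.009 in the limma runs.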
